A study of Mus musculus with 24 samples.

How the data were processed

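Spinal cord of mice was sampled on days 3, 7 and 14 after spared nerve injury and after sham surgery, with 3 replicates in each of 4 groups and an input and an m6A-enriched library per replicate, 24 samples in all. Sham is labelled day 3 only. Grouping follows the sample labels, and the analysis used processed tables rather than reads.

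The gene table holds FPKM per the file headers, for 32884 genes in the 12 input libraries. The peak tables give 1 list per group; whether replicates were pooled before peak calling is not stated in the sources used here. Per the file headers, each peak has a width as block sizes and span on a stranded chromosome, a score as lg.p and lg.fdr, base 10 logarithms of the p and of the false discovery rate, and a fold enrichment of enriched over input as a ratio. Per the submitters' processing notes the tools HISAT2, ChIPseeker, StringTie and edgeR were used; no versions or settings are given. The peak caller and the genome build are not given in the sources used here. Values per enriched library were not used here, since the peak tables carry no column for single libraries. Coordinates are those of the tables: of 26171 gene symbols matched to GRCm38.p6 RefSeq genes, 99.92% overlapped the gene of the same name. Gene identifiers were in the reference name table for 99.7%, with the same symbol for 97.1%.

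Depth per library is unknown because only FPKM was analysed here, so no counting error could be computed. Precision comes from the spread between libraries alone.

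Genes with a mean FPKM of at least 0.5 over the 12 input libraries were tested (15564). Values were log2(FPKM + 0.5) and were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) as 4 group means in 1 fit. Contrasts were each injured day against sham, each pair of injured days, and the mean of the injured days against sham, with a moderated F test over the injury contrasts. Adjusted p-values are Benjamini-Hochberg values within each contrast, and a gene passed below 0.05. Standard errors are the moderated ones of the fit, and levels are means with the SD of 3 libraries.

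A set of 36 gene lists with 477 genes was written before the data were opened, covering cell types, pathways and m6A enzymes. Lists with at least 5 tested members (33 lists, 99 tests over 3 contrasts) were tested with camera at a preset correlation of 0.01, adjusted over all tests together. Camera with an estimated correlation was run beside it. Members were also adjusted over the list alone.

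Genes were named by a rule fixed beforehand: per injury contrast, up to 12 higher and 8 lower genes with the largest fold change among those that passed, with non-overlapping values, a mean FPKM of at least 1 in either group and no predicted name. List members that passed, the 2 members with the smallest p in lists without 1, and all m6A enzymes could be named too. Cd180, C1qa, Ctla2a, Ly86 on day 7, the genes between injured days, those of the averaged contrast, the clock genes, Gm23935, Lars2, genes of lung and liver, and peaks with no shared base were named after their values were seen.

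Overlap of calls between days was set beside 100 simulated draws in which unchanged groups shared the same sham error. Peaks of 2 groups were shared when they overlapped reciprocally by at least 50% on the same strand (bedtools 2.31.1). A stricter peak list had a fold enrichment of at least 2 and a p of at most 1e-05. RNA changes of genes with gained or lost peaks were compared with 10000 random gene lists matched on level in 50 bins. For each injured day the 5 gained and 5 lost peaks of highest fold enrichment in genes with a mean FPKM of at least 1 could be named.

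The steps were tested on simulated data with known changes. Of genes changed by a log2 of 0.5, 1 and 2, the fit recovered 32.8, 65.7 and 93.9% in the day 3 contrast, 22.4, 77.6 and 92.4% on day 7, and 20.9, 64.2 and 97% on day 14. False calls were 5.19, 7.25 and 3.2% of calls. The simulated noise was independent between libraries, with the same spread in every library for a gene. It held no near-identical libraries and no shift shared by day 7 library 3 and sham library 3. These rates therefore need not hold for the data here.

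Alternatives fixed beforehand were pseudocounts of 0.1 and 1, no filter and a filter of 5, rescaling to TPM, median-of-ratios and quantile scaling, a replicate block, fits of 2 groups, array weights, robust eBayes, an unadjusted p with a log2 fold change of at least 1, leaving out each library, a stricter or merged peak list, overlap of 1 base or 80%, and equal numbers of strongest peaks. After the data were seen, 4 more were added: leaving out day 7 library 3 and sham library 3, a preparation term for them, averaging near-identical libraries into 6 samples, and averaging with the term. The preparation term marks those libraries by their values, since the labels name no preparation. Overlap of exonic blocks was also added. Splits of the libraries were made as 10 per pair of groups and 100 over 12 libraries.

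Sequence motifs were left out because no genome sequence was used here. Tests of m6A between groups were left out because each group has 1 peak list.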

Results

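Spinal cord RNA was profiled in mice on days 3, 7 and 14 after spared nerve injury, a model of neuropathic pain, and in sham-operated mice labelled day 3. Each of the 4 groups had 3 input RNA-seq libraries and 3 libraries of RNA enriched for N6-methyladenosine (m6A), 24 in all. Levels of 32884 genes were given as FPKM for the 12 input libraries, and m6A was given as 1 peak list per group. FPKM summed to 180340 to 201358 per library, and 13273 to 13511 genes per library had an FPKM of at least 1. Read counts were not used here, so sequencing depth is unknown. Sham cords from days 7 and 14 were not among the samples, so injury and time are compared against day 3 sham only.

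**Figure D1:**
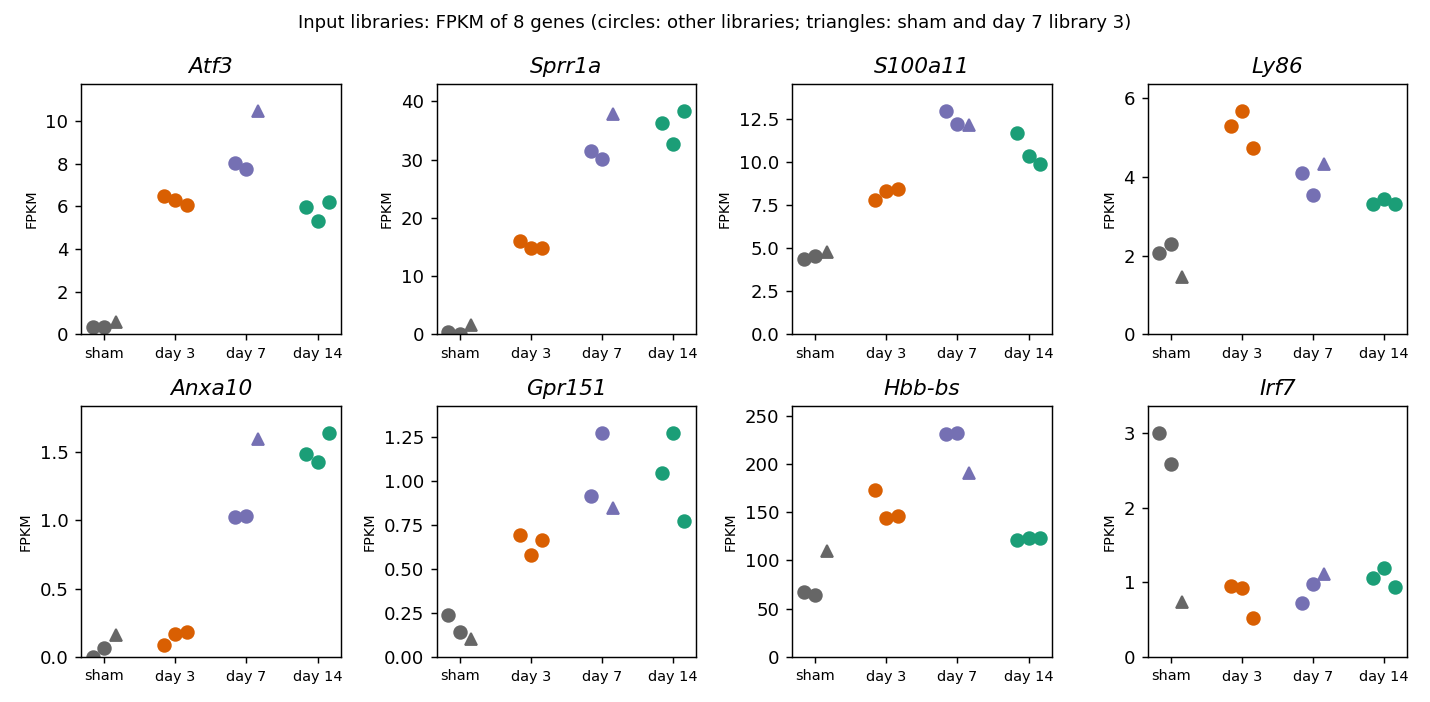
Genes by FPKM in each of the 12 input libraries, coloured by group.

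Day 7 library 3 and sham library 3 stood apart from the other 10. Gm23935, an RNA without a poly(A) tail, was at 0.501 and 1.43 FPKM in these 2 libraries, at 325 to 515 FPKM in the other injured libraries and at 3812 and 3891 FPKM in sham libraries 1 and 2. Lars2 was at 1.18 and 1.11 FPKM in the 2 libraries, at 11.9 to 18.7 FPKM in the other injured ones and at 108 FPKM in sham libraries 1 and 2. Every comparison with sham given below without the libraries that stood apart rests on those 2 sham libraries. Sham libraries 1 and 2 thus differ from all injured ones in these RNAs. Across genes, the 2 libraries that stood apart correlated with the others at 0.925 to 0.943 and with each other at 0.983. Principal component 1 held 52.8% of the variance. The remaining libraries of each group were near-identical: for the 93 genes at 200 FPKM or more, the ratio of 2 libraries spread by 1.22 to 1.77% within these groups, by 3.5 to 7.55% between groups and by 43.3 to 49.3% against the libraries that stood apart. At 1 to 2 FPKM (2256 genes) the spreads within and between groups were close, at 17.8 to 20.2% and 18.8 to 23.8%. Correlations were 0.980 to 0.988 within and 0.979 to 0.988 between groups, leaving aside the libraries that stood apart. Whether the 3 libraries of a group came from different mice is not stated in the sources used here. All p-values below measure only the spread between libraries, which may be technical.

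**Figure D2:**
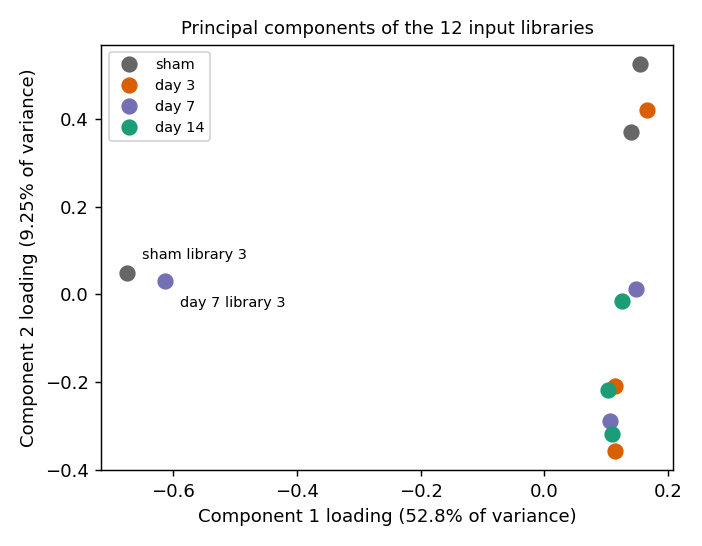
Principal components of the 12 input libraries. Day 7 library 3 and sham library 3 are named.

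On day 3, markers of axotomised neurons and of myeloid cells were higher in injured cord than in sham. Atf3, a transcription factor induced by axon damage (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), rose from 0.422 ± 0.141 to 6.27 ± 0.224 FPKM (mean ± SD, n = 3 per group), a log2 fold change of 2.89 ± 0.13 (SE, adjusted p = 1.03e-05). Sprr1a, which promotes axon outgrowth (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), rose from 0.716 ± 0.753 to 15.2 ± 0.646 FPKM (3.87 ± 0.32, adjusted p = 0.00178). Ccl7, a monocyte chemokine (1.67 ± 0.20, adjusted p = 0.0161), Ly86, a partner of a Toll-like receptor homologue (1.25 ± 0.13, adjusted p = 0.00708), Bin2, a myeloid membrane-shaping protein (0.94 ± 0.13, adjusted p = 0.0355), and Tmem119, a microglial marker (0.66 ± 0.09, adjusted p = 0.0355), also rose. S100a11, a calcium-binding protein (ENSMUSG00000027907, chromosome 3, 93520488 to 93526287), went from 4.58 ± 0.181 to 8.21 ± 0.328 FPKM (0.78 ± 0.08, adjusted p = 0.00586), and Dbp, a clock-controlled transcription factor, from 5.89 ± 0.588 to 12.3 ± 0.726 FPKM (1.01 ± 0.11, adjusted p = 0.012). Slc5a7, the choline transporter of cholinergic neurons (ENSMUSG00000023945, chromosome 17, 54273590 to 54299034), fell by 0.49 ± 0.07 (log2, adjusted p = 0.0355), from 14.9 ± 0.964 to 10.4 ± 0.411 FPKM. In limma-trend fits of log2(FPKM + 0.5) to 15564 genes, 8 rose and 1 fell, and 971 had an unadjusted p below 0.05. The total was 3 without any 1 of the day 3 libraries, 40 without day 7 library 3 and 27 without sham library 3. Without both libraries that stood apart 624 genes rose and 477 fell, all 9 genes among them, and Lars2 was lower there (-2.52). Averaging near-identical libraries into 6 samples, which leaves 2 residual degrees of freedom and little power, left 0 of the 9 past the threshold in limma (51 genes with an unadjusted p below 0.05). All 9 kept their direction, which averaging the same values largely fixes, with Atf3 at 2.83.

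Among gene groups on day 3, 2 of 18 tested injured-neuron genes rose (Atf3, Sprr1a) and 16 did not pass; 6 passed when adjusted over the list alone. Gal, a neuropeptide induced by axotomy, was at 3.98 FPKM in sham and 10.6 on day 3 (log2 1.44) without passing. The injured-neuron median was 0.20 (camera, adjusted p = 2.9e-08; adjusted p = 0.034 with an estimated correlation). It was 0.13 without both libraries that stood apart (adjusted p = 0.012 with an estimated correlation). Homeostatic microglial genes had 1 of 12 higher (Tmem119), 9 when adjusted over the list alone, and a median of 0.48 (adjusted p = 4.9e-10; adjusted p = 0.046 with an estimated correlation). Complement genes had 0 of 8 past the threshold in limma (4 adjusted over the list alone), a median of 0.47 and an adjusted p of 1.2e-08 (adjusted p = 0.042 with an estimated correlation), with C1qb at 0.73. Phagocytosis and lysosome genes, including Laptm5 (0.57), had 0 of 14 (3 adjusted over the list alone) and a median of 0.24 (adjusted p = 0.00025; adjusted p = 0.04 with an estimated correlation). Microglial activation genes, including Itgam (0.74), had 0 of 14 (8 adjusted over the list alone) and a median of 0.46, and their adjusted p of 1.8e-09 became adjusted p = 0.053 with an estimated correlation (0.023 without both libraries that stood apart). Chemokine and cytokine genes had 1 of 9 higher (Ccl7) and a median of 0.23 (adjusted p = 0.0021, or 0.06 with an estimated correlation). Without both libraries that stood apart camera did not call that list (median 0.24, adjusted p = 0.073, or 0.28 with an estimated correlation).

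On day 7, axon-injury, haemoglobin and myeloid genes were higher in injured cord than in sham. Sprr1a reached 33.2 ± 4.16 FPKM (log2 fold change 4.96 ± 0.32, adjusted p = 0.000106, n = 3 per group), Atf3 8.75 ± 1.51 (3.33 ± 0.13, adjusted p = 2.49e-06) and S100a11 12.5 ± 0.477 (1.35 ± 0.08, adjusted p = 4.08e-05). Anxa10, a phospholipid-binding annexin (ENSMUSG00000031635, chromosome 8, 62057042 to 62123150; 1.57 ± 0.15, adjusted p = 0.00364), Tubb6, a beta-tubulin (1.44 ± 0.19, adjusted p = 0.0205), and Gpr151, a neuronal orphan receptor (1.19 ± 0.15, adjusted p = 0.0176), rose. Haemoglobin genes Hba-a1 (1.52 ± 0.16, adjusted p = 0.00862), Hba-a2 (1.49 ± 0.17, adjusted p = 0.0108), Hbb-bs (1.47 ± 0.18, adjusted p = 0.0137) and Hbb-bt (1.49 ± 0.20, adjusted p = 0.025) rose together with Alas2, which starts erythroid haem synthesis (1.23 ± 0.18, adjusted p = 0.0387). Reads of Hba-a1 and Hba-a2, and of Hbb-bs and Hbb-bt, are split between near-identical copies, so each share is uncertain. Myeloid genes that rose were Ccl7 (1.71 ± 0.20, adjusted p = 0.0108), Ly86 (0.89 ± 0.13, adjusted p = 0.0387), its partner Cd180 (0.67 ± 0.10, adjusted p = 0.0436) and the complement gene C1qa (0.71 ± 0.08, adjusted p = 0.0108). Ctla2a, a cathepsin inhibitor, rose by 0.79 ± 0.10 (adjusted p = 0.0157). In limma 16 genes rose and 0 fell (393 with an unadjusted p below 0.05). All 16 were higher in day 7 libraries 1 and 2 than in sham libraries 1 and 2. They were also higher in day 7 library 3 than in sham library 3. The fit that chose these genes used the same libraries. Disagreement between the 2 differences would have widened its spread, so their shared sign is no separate support. Across all genes those 2 differences correlated at 0.0838 (Pearson; genes are not independent replicates). The count was 4 without day 7 library 1, 5 without sham library 2, 6 without day 7 library 2, 26 without sham library 3 and 173 without both libraries that stood apart. Averaged into 6 samples, with 2 residual degrees of freedom, 0 of the 16 passed in limma (72 genes with an unadjusted p below 0.05). All 16 kept their direction, which averaging the same values largely fixes, with S100a11 at 1.33. For Atf3 the day 7 difference was 3.32 in libraries 1 and 2 and 3.34 in library 3. Adding a preparation term to the 6 samples leaves each gene only the gap between such values as residual. That fit therefore cannot stand as a test at sample level.

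Erythroid genes had 5 of 5 higher on day 7 and a median of 1.49 (adjusted p = 4.7e-31; adjusted p = 0.0089 with an estimated correlation). Injured-neuron genes had 2 of 18 higher, 6 adjusted over the list alone, and a median of 0.17 (adjusted p = 6.5e-17; adjusted p = 0.0089 with an estimated correlation). Homeostatic microglial genes had 0 of 12 past the threshold in limma but 10 adjusted over the list alone, with Cx3cr1 at 0.52, and a median of 0.49 (adjusted p = 6.7e-25; adjusted p = 0.0089 with an estimated correlation). Microglial activation genes, among them Itgam (0.82), had 0 of 14, 6 adjusted over the list alone, and a median of 0.41 (adjusted p = 9.6e-14; adjusted p = 0.034 with an estimated correlation). Complement genes had 1 of 8 higher (C1qa), 4 adjusted over the list alone, and a median of 0.29 (adjusted p = 7e-09; adjusted p = 0.042 with an estimated correlation). Chemokine and cytokine genes (1 of 9, Ccl7; median 0.30; adjusted p = 3.9e-08) and phagocytosis genes (0 of 14; 2 adjusted over the list alone; median 0.17; adjusted p = 1.4e-09) each kept adjusted p = 0.0089 with an estimated correlation. These values were 0.17 for the chemokines (median also 0.17) and 0.008 for phagocytosis without both libraries that stood apart.

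On day 14, Sprr1a, Atf3 and S100a11 were again higher in injured cord than in sham. Sprr1a stood at 35.8 ± 2.93 FPKM (log2 fold change 5.07 ± 0.32, adjusted p = 8.48e-05, n = 3 per group), Atf3 at 5.83 ± 0.459 (2.79 ± 0.13, adjusted p = 1.47e-05) and S100a11 at 10.7 ± 0.943 (1.13 ± 0.08, adjusted p = 0.000116). Anxa10 (1.82 ± 0.15, adjusted p = 0.000725), Ctla2a (1.57 ± 0.10, adjusted p = 8.48e-05), Tubb6 (1.48 ± 0.19, adjusted p = 0.0248), Gpr151 (1.21 ± 0.15, adjusted p = 0.0248) and Dbp (1.01 ± 0.11, adjusted p = 0.0093) rose as well. Npy, a peptide of inhibitory interneurons also induced in injured afferents, was at 16.8 FPKM in sham and 33 on day 14 (log2 0.98, adjusted p = 0.274) and did not pass. In limma 8 genes rose and 0 fell (765 with an unadjusted p below 0.05). The count was 5 without day 14 library 2 or sham library 2, 21 without sham library 3 and 733 without both libraries that stood apart. Averaged into 6 samples, with 2 residual degrees of freedom, 0 of the 8 passed in limma (47 genes with an unadjusted p below 0.05). All 8 kept their direction, which averaging the same values largely fixes, with Ctla2a at 1.62.

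Injured-neuron genes held 2 of 18 higher on day 14, 9 adjusted over the list alone, with Gap43 at 0.42 and a median of 0.26 (adjusted p = 6.9e-10; adjusted p = 0.026 with an estimated correlation). Oligodendrocyte genes were lower on day 14: myelin genes had a median of -0.18 (adjusted p = 1.5e-05; adjusted p = 0.04 with an estimated correlation) and precursor genes -0.27 (adjusted p = 0.00014; adjusted p = 0.034 with an estimated correlation). In limma 0 of the 14 myelin and 0 of the 10 precursor genes passed, and 3 of each did when adjusted over the list alone, among them Mal (-0.42), Gjc3 (-0.46) and Olig2 (-0.48). On day 3 the precursor median was -0.18 (adjusted p = 0.0024; adjusted p = 0.053 with an estimated correlation) and the myelin median -0.05 (adjusted p = 0.013; adjusted p = 0.2 with an estimated correlation). The estimated correlation gave 0.008 and 0.0046 without both libraries that stood apart, with a myelin median of -0.15. Myelin genes moved the other way on day 7, with a median of 0.09 (adjusted p = 0.026; adjusted p = 0.24 with an estimated correlation), or 0.04 without both libraries that stood apart (adjusted p = 0.11 with an estimated correlation). Microglial lists still shifted up, but the homeostatic (median 0.26, adjusted p = 6.5e-05) list gave adjusted p = 0.19 with an estimated correlation and the activation list (0.37, adjusted p = 3.6e-06) gave adjusted p = 0.14 with an estimated correlation. Complement (0.39, adjusted p = 0.00023) gave adjusted p = 0.18 with an estimated correlation, and chemokines (0.30, adjusted p = 0.0061) gave adjusted p = 0.095 with an estimated correlation. Without both libraries that stood apart the estimated correlation gave 0.036 for the homeostatic, 0.084 for the activation (median 0.18), 0.043 for the complement (median 0.23) and 0.43 for the chemokine list. Camera with a fixed correlation called 17, 14 and 17 of 33 lists on days 3, 7 and 14, and 4, 7 and 3 with an estimated correlation. Fold changes are on the log2(FPKM + 0.5) scale and understate change in genes of low level.

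**Figure D3:**
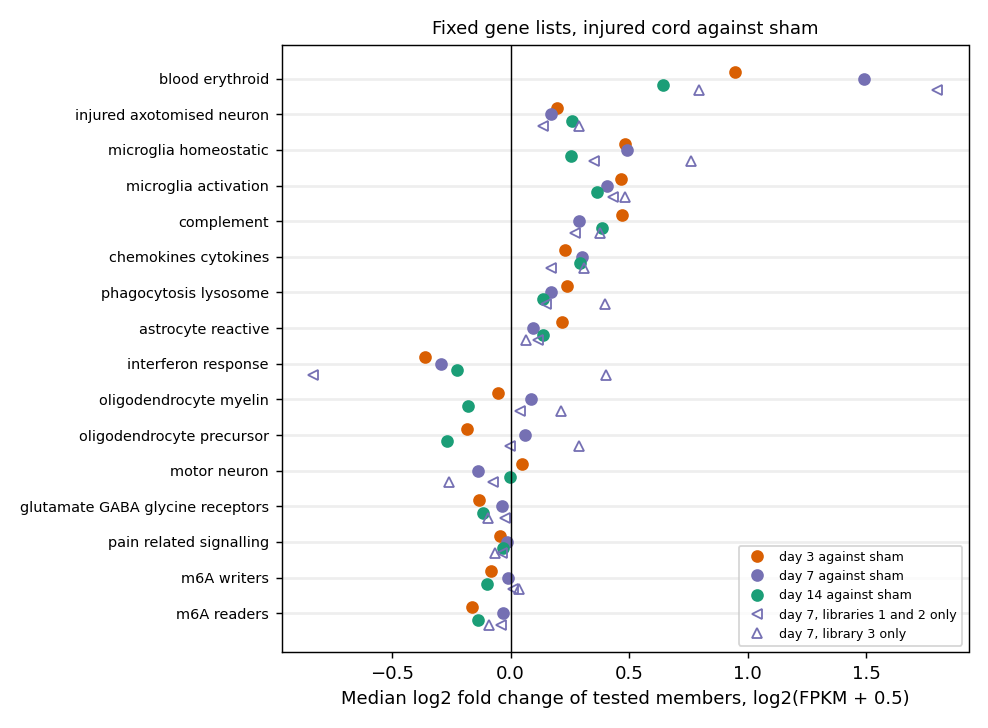
Median log2 fold change of fixed gene lists on days 3, 7 and 14 against sham.

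Several further lists shifted without 1 gene passing, and with all 12 libraries each lost its call with an estimated correlation. Erythroid genes were up on day 3 (median 0.95, adjusted p = 1.7e-07; adjusted p = 0.14 with an estimated correlation) and day 14 (0.64, adjusted p = 4.6e-06; adjusted p = 0.19 with an estimated correlation). Interferon-response genes such as Ifit1 (-1.05, -0.85 and -0.77 on days 3, 7 and 14) had medians of -0.36 (adjusted p = 1.2e-07), -0.29 (3.5e-08) and -0.23 (0.00048); these gave adjusted p = 0.24, 0.22 and 0.43 with an estimated correlation. On day 7 the sign of the interferon genes differed between libraries, with a median of -0.83 in libraries 1 and 2 and 0.40 in library 3. Without both libraries that stood apart the estimated correlation kept the calls of the interferon genes (adjusted p = 0.0042, 0.0038 and 0.0046 on days 3, 7 and 14; medians -0.88, -0.83 and -0.63) and of the erythroid genes (0.023 on days 3 and 14). Cytosolic ribosomal protein genes had medians of 0.35 (adjusted p = 2.9e-08), 0.12 (0.002) and 0.28 (1e-04), with adjusted p = 0.24, 0.48 and 0.43 with an estimated correlation. Rplp1 was at 354 FPKM in sham libraries 1 and 2 and 87.1 in library 3. For the ribosomal protein genes too, the estimated correlation kept the calls without both libraries that stood apart (adjusted p = 0.0038, 0.0046 and 0.0068), with smaller medians of 0.20, 0.11 and 0.09. Transmitter receptor genes were lower on day 3 (-0.13, adjusted p = 0.00028; adjusted p = 0.41 with an estimated correlation) and day 14 (-0.12, adjusted p = 0.0031; adjusted p = 0.48 with an estimated correlation). Their medians were -0.02 (adjusted p = 0.019; adjusted p = 0.11 with an estimated correlation) and -0.00 (adjusted p = 0.81) without both libraries that stood apart. Mitochondrially encoded genes had a median of -0.29 on day 7 (adjusted p = 2.1e-05; adjusted p = 0.4 with an estimated correlation), but 0.27 in libraries 1 and 2 and -1.34 in library 3. Without the libraries that stood apart that list turned upward (adjusted p = 0.0028; adjusted p = 0.28 with an estimated correlation). Motor-neuron genes, apart from Slc5a7 on day 3, held no gene past the threshold, and their day 7 median of -0.14 (adjusted p = 0.0092) gave adjusted p = 0.43 with an estimated correlation. Without both libraries that stood apart their medians were -0.11, -0.07 and -0.17 on days 3, 7 and 14 (adjusted p = 0.025, 0.047 and 0.0065 with an estimated correlation). Pain-related signalling genes were not called on any day (16 tested; medians -0.05, -0.01 and -0.03; adjusted p = 0.34, 0.44 and 0.36); Scn9a, a sodium channel of nociceptors, was at 0.46 on day 7 and did not pass.

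The enzymes of m6A showed no change that passed. Writers had medians of -0.08, -0.01 and -0.10 on days 3, 7 and 14 (12 tested; adjusted p = 0.32, 0.87 and 0.25), with the methyltransferase Mettl3 at 0.10, 0.06 and 0.17 and its partner Mettl14 at -0.19, -0.02 and -0.24. The demethylases stayed level: Alkbh5 at 0.01, -0.03 and 0.01, Fto at 0.01, -0.04 and 0.06. Readers had medians of -0.16 on day 3 (adjusted p = 0.022; adjusted p = 0.51 with an estimated correlation) and -0.14 on day 14 (adjusted p = 0.0074; adjusted p = 0.48 with an estimated correlation), with 0 of 9 genes past the threshold in limma. Neither was called without both libraries that stood apart (medians -0.02 and -0.02; adjusted p = 0.35 and 0.24).

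Between injured days, few genes passed in the fit of all 12 libraries. Anxa10 was higher on day 7 than on day 3 (1.40 ± 0.15, adjusted p = 0.0217) and higher on day 14 than on day 3 (1.65 ± 0.15, adjusted p = 0.00946). Ctla2a was higher on day 14 than on day 7 (0.78 ± 0.10, adjusted p = 0.0441) and day 3 (0.90 ± 0.10, adjusted p = 0.0238), from 2.87 through 3.18 to 5.81 FPKM. Mt2, a metal-binding stress protein, was lowest on day 7: 255 ± 1.36, 179 ± 7.07 and 246 ± 2.49 FPKM on days 3, 7 and 14 (-0.51 ± 0.05, adjusted p = 0.0217 for day 7 against day 3; 0.46 ± 0.05, adjusted p = 0.0307 for day 14 against day 7). S100a8 and S100a9, neutrophil calcium-binding proteins, were lower on day 14 than on day 7 (-1.40 ± 0.16, adjusted p = 0.0307, and -1.59 ± 0.14, adjusted p = 0.00798), as was Hmgcs1, of cholesterol synthesis (-0.46 ± 0.06, adjusted p = 0.0441). Against sham the cholesterol synthesis list had medians of 0.09 on day 7 (adjusted p = 0.00084; adjusted p = 0.47 with an estimated correlation) and -0.02 on day 14 (adjusted p = 0.0074; adjusted p = 0.51 with an estimated correlation). Without both libraries that stood apart the cholesterol medians were -0.12, 0.06 and -0.23 on days 3, 7 and 14 (adjusted p = 0.01, 0.023 and 0.0038 with an estimated correlation), and day 3 was then lower, where it was not called before. These genes were named after their values were seen (n = 3 per group; 631, 694 and 273 genes had an unadjusted p below 0.05 for day 7 against 3, 14 against 7 and 14 against 3). Counts of 2, 5 and 2 became 317, 418 and 309 without both libraries that stood apart, and 8, 15 and 4 without sham library 3 alone. They were 0, 0 and 0 in limma without any 1 of the day 14 libraries (at least 214 genes with an unadjusted p below 0.05). Without day 7 library 1 or 2 they were 0, 0 and 1. In limma fits of only the 2 groups compared they were 0, 0 and 155 (509, 555 and 2385 genes with an unadjusted p below 0.05). The 155 are for day 14 against 3, where neither group holds a library that stood apart. The low count in the fit of all libraries is therefore no evidence that few genes differed. Leaving out any 1 of the day 3 libraries left 0 for day 7 against 3, 1 or 2 for day 14 against 7 and 0 for day 14 against 3. Averaged into 6 samples, 0 of these calls passed in limma (57, 29 and 29 genes with an unadjusted p below 0.05), all in the same direction.

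Averaged over the injured days, 18 genes rose and 2 fell against sham (753 with an unadjusted p below 0.05). The genes that fell were Slc5a7 (-0.39 ± 0.05, adjusted p = 0.0272) and Erbb3, a neuregulin receptor of oligodendrocyte-lineage and Schwann cells (-0.39 ± 0.06, adjusted p = 0.0338). Nav2, a regulator of neurite growth (0.50, adjusted p = 0.0377), and Mettl7a3, a methyltransferase-like protein (0.94, adjusted p = 0.0481), rose in this contrast. A moderated F test found 16 genes differing among the 4 groups (650 with an unadjusted p below 0.05). Without the libraries that stood apart the totals were 687 and 1066, and without sham library 2 they were 5 and 8. Without any 1 library of day 3 or day 14, or day 7 library 1 or 2, 11 to 13 genes passed the averaged contrast and 0 of them were lower. Neither Slc5a7 nor Erbb3 passed there, and the F test gave 5 to 11. Averaged into 6 samples 0 genes passed either test in limma (91 and 50 with an unadjusted p below 0.05).

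Atf3, Sprr1a and S100a11 rose on all 3 days. Shared higher genes numbered 5 for days 3 and 7, 4 for days 3 and 14 and 7 for days 7 and 14, against 0.0082, 0.0041 and 0.0082 for independent lists. All 3 comparisons use the same sham libraries, and when a shared sham error alone was simulated the mean overlap was 7.81, 6.69 and 7.51. That simulation holds no shift shared by sham library 3 and day 7 library 3, and none was made without them. Whether the overlap exceeds what shared controls give is therefore left open. With 3 sham libraries the controls could not be split into separate sets. Covariance of the fold changes across genes was 0.0245, 0.0508 and 0.0251, against 0.0496, 0.0494 and 0.0495 in the simulation. It was below the simulated value for days 3 and 7 (by -0.0251) and for days 7 and 14 (by -0.0244). For days 3 and 14 it was near that value (difference 0.00142, simulated SD 0.0022).

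Peak lists of m6A held 32669 peaks in sham, 40195 on day 3, 34136 on day 7 and 38655 on day 14, in 15924, 18584, 16737 and 18097 genes. Among peaks with a fold enrichment of at least 2 and a p of at most 1e-05 the numbers were 21808, 22097, 20957 and 21959. The largest share of peaks lay in 3′ UTRs (48.4, 50.7, 49.3 and 51.5%), then other exons (36.3, 31.8, 36.5 and 31.3%) and 5′ UTRs (15.3, 17.5, 14.2 and 17.2%). Median fold enrichment was 6.03, 4.54, 5.37 and 4.52. With 1 list per group no test between groups is possible, and the counts carry no error.

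**Figure D4:**
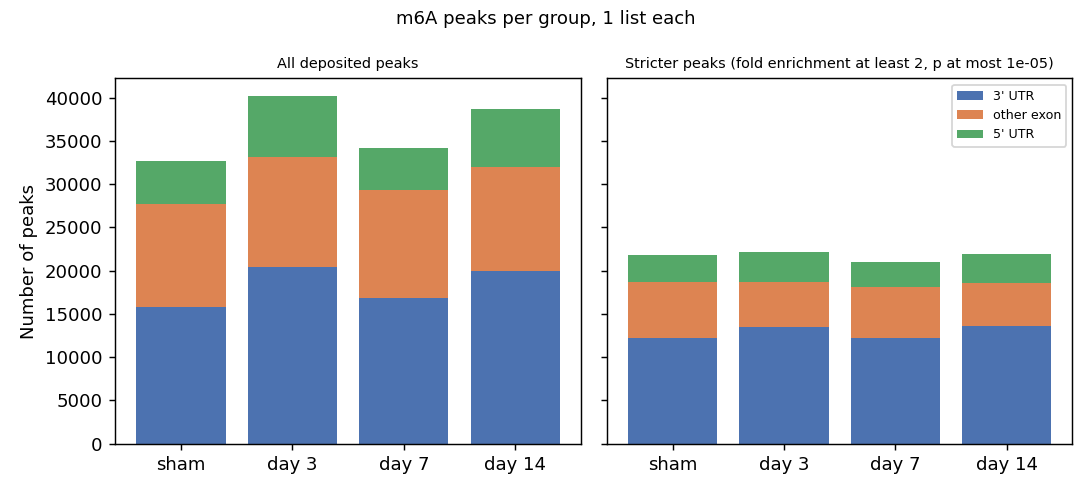
Number of m6A peaks in each group by place in the transcript (3′ UTR, other exon, 5′ UTR), for all peaks and for the stricter peaks.

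Against sham, 24614 peaks were gained and 17077 lost on day 3, 17103 and 15622 on day 7, and 22760 and 16772 on day 14 (reciprocal overlap below 50% on the same strand). Many were the same site with other edges: a peak in Syncrip, an RNA-binding protein, spanned 88480963 to 88482574 on chromosome 9 on day 3 (fold enrichment 361) and 88482064 to 88482574 in sham (331), and so counted as gained and as lost. Fam98b, of the transfer RNA ligase complex, likewise had a 7549 base span on day 3 (fold enrichment 469) and 3349 bases in sham (91.9). Counting any shared base as overlap left 14639 gained and 4465 lost on day 3, 8951 and 6191 on day 7, and 13383 and 4674 on day 14. The lost peak of highest fold enrichment among genes with a mean FPKM of at least 1, in the 3′ UTR of Nanp, a sialic acid phosphatase (chromosome 2, 151029982 to 151030904, 1210 in sham), also shared bases with longer peaks on each injured day. Stricter peaks with no base in the sham list numbered 3452, 1959 and 3380 on days 3, 7 and 14, for example in Sh3glb2, of endosome sorting (97.3 on day 3), Nkain1, a sodium pump partner (65.7 on day 3 and 130 on day 14), and Eno1b, an enolase (87.4 on day 7). Stricter sham peaks with no base afterwards numbered 612, 1373 and 573, for example in Zbed4 (84.4), absent on days 3 and 7, and Rab35, of membrane recycling (151), absent on day 7. Gained peaks were weaker than shared ones: median fold enrichment 3.79 against 5.54, 4.7 against 5.9 and 3.66 against 5.76. Stricter peaks of day 3 overlapped those of day 14 for 77.2%, those of day 7 for 64.2% and those of sham for 53.9%. Days 3 and 14 thus shared more with each other than either did with sham. Stricter peaks of day 7 overlapped those of day 3 for 67.7%, of day 14 for 68.3% and of sham for 64.2%. Sham and day 7 each hold an input library that stood apart, and days 3 and 14 hold none. Injury and whatever set those input libraries apart therefore cannot be separated in these shares.

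Among genes named above, Sprr1a, S100a11 and Mt2 carried strict 3′ UTR peaks on all 3 injured days and no strict peak in sham. Mt2 had a mean of at least 179 FPKM in every group, whereas Sprr1a was at 0.716 in sham. Atf3 had 1 strict peak in every list (2, 1, 1 and 1 peaks in all). Haemoglobin genes and Alas2 had 0 peaks in every list. Mettl14 had 0 peaks in sham and 3, 2 and 2 on days 3, 7 and 14, of which 1 was strict on each day; Alkbh5 had 2 in sham and 2, 1 and 2 afterwards, of which 2 were strict in sham and 0 afterwards. The gene named with a peak differed from the gene its annotation assigned for 22.2 to 22.6% of peaks. Every peak whose named gene had FPKM values lay inside that gene (32389, 39813, 33793 and 38282 peaks in sham and on days 3, 7 and 14).

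Genes with gained peaks differed little in RNA change from random gene lists matched on level. Those lists were drawn from all tested genes, the genes with gained peaks included. On day 3 these were 10291 of 15564, so the random lists held many of the same genes and their ranges were narrow. Their median log2 fold change was 0.0156 on day 3, below the 0.0255 to 0.0317 that held 95% of random gene lists matched on level, -0.00459 against 0.00399 to 0.00771 on day 7, and 0.0225 against 0.0287 to 0.0356 on day 14. Genes with lost peaks had medians of -0.00839, -0.00202 and 0.00478, also below their random lists. Genes with a peak after injury and none in sham went the other way: 0.1 against 0.0232 to 0.0457 on day 3 and 0.0796 against 0.0249 to 0.0492 on day 14. Day 7 gave 0.000405 against -0.000682 to 0.0149. Genes with a peak in sham and none after injury were at 0.0461 against -0.0166 to 0.0568 on day 3, 0.0231 against -0.00228 to 0.0174 on day 7 and 0.00114 against -0.0153 to 0.0568 on day 14. Values above random lists were thus not limited to gained peaks. Without the libraries that stood apart the day 3 median stayed above its random lists (0.0301 against 0.0134 to 0.025). Genes with a peak in sham and none on day 3 also lay above theirs (0.0596 against -0.00659 to 0.0344). The day 14 median lay among its random lists (0.0187 against 0.0177 to 0.0271). The input libraries enter both the peak calls and the RNA levels, and genes are not independent replicates.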

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

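The values between injured days were singled out because adjusted p passed in a direct comparison of 2 injured groups; they were chosen after the result was seen. Anxa10 differed by 1.40 between days 7 and 3 and by 1.65 between days 14 and 3. Ctla2a differed by 0.78 between days 14 and 7 and by 0.90 between days 14 and 3. Mt2 differed by -0.51 between days 7 and 3 and by 0.46 between days 14 and 7. Between days 14 and 7, S100a8 differed by -1.40, S100a9 by -1.59 and Hmgcs1 by -0.46. No explanation was tested for Anxa10, Ctla2a, Mt2 or Hmgcs1.

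All 4 tests of why day 7 library 3 and sham library 3 stood apart were chosen after the result was seen. An exchange of their labels is excluded, since the smaller of the Atf3 and Sprr1a log2 ratios of day 7 library 3 over sham library 3 was 3.34. The myelin genes could not decide on a different cell make-up. Their shifts had an SD of 0.506 around a median of -0.35, from -1.05 for Mag to 0.50 for Ermn. Shifts of all genes had an SD of 0.562, so such scatter is not particular to myelin genes and could hide a common shift. Genes of other cell types were not used in this test. A shared preparation or processing difference is consistent with a correlation across genes of 0.8 between the shifts of the 2 libraries. Lower uptake of RNA without a poly(A) tail is consistent with a median shift of -3.58 for 6 such genes, against -0.58 to 0.36 for random genes of like level.

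Haemoglobin transcripts were most abundant on day 7, and both tests of this were chosen after the result was seen. More blood in the day 7 cords is consistent with the neutrophil genes Ngp, S100a8 and S100a9, whose median day 7 difference was 0.84 in day 7 library 3 against sham library 3 and 0.86 in the other libraries. On day 14 the same genes were below sham libraries 1 and 2 (S100a9 at 1.7 against 2.64 FPKM, S100a8 at 0.572 against 0.968, Ngp at 0.359 against 0.563) while Hbb-bs was above them (123 against 66.1), so blood is left open for that day. Sham library 3 had Hbb-bs at 109.8 FPKM, nearer to day 14. The libraries that stood apart do not account for the day 7 rise, as Hbb-bs differed by 1.80 without them. The size of the rise did vary, as day 7 library 3 was 0.80 above sham library 3 (log2).

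The day 3 and day 14 peak lists were longer than those of sham and day 7, with a ratio of mean numbers of 1.18; the test of weak peaks was chosen after the result was seen, and that of input levels before. More weak peaks passing the caller is consistent with a ratio of 1.03 among stricter peaks. Different input in the libraries that stood apart is consistent with the 1205 genes with peaks on days 3 and 14 alone, whose median shift in those libraries was -0.30 against -0.12 to -0.02 for random genes of like level (886 tested). These explanations were not told apart.

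Most libraries of a group were near-identical, so splits that mix groups tend to give fewer calls whatever made the groups differ. The splits therefore cannot tell injury from other differences between the samples. For the pairs of groups only 10 splits into 3 and 3 exist, which cannot give a share under 0.05. The real grouping gave 9 genes on day 3 (highest other split 3), 16 on day 7 (1), 8 on day 14 (0), 2 for day 7 against 3 (0), 5 for day 14 against 7 (1) and 2 for day 14 against 3 (0), so 1 of 10 splits reached each value. Over 100 splits of the 12 libraries into 4 groups, 1 reached the 16 genes of the F test (highest other 9). For the mean of the injured days 3 of 100 reached 20 genes; the highest other gave 6704 and put both libraries that stood apart into the same group.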

How the results depend on the processing

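The cause of the changes below was not tested. Counts for day 3, day 7 and day 14 against sham were 9, 16 and 8; for day 7 against 3, day 14 against 7 and day 14 against 3 they were 2, 5 and 2; for the mean of the injured days 20 and for the F test 16; shared calls were 5, 4 and 7. A pseudocount of 0.1 gave 1 for day 7 against 3 and 3 for day 14 against 7. No filter gave 3 for day 14 against 7 and 4 for day 14 against 3. A filter of 5 FPKM gave 8 on day 7, 4 on day 14, 1 for day 7 against 3, 0 for day 14 against 3, and 3 shared calls for days 3 and 7 and 3 for days 7 and 14. TPM gave 1 for day 7 against 3 and 1 for day 14 against 3. Quantile scaling gave 0 for day 7 against 3 and 9 in the F test. With replicate number as a block there were 5 on day 3, 9 on day 7, 1 for day 7 against 3, 0 for day 14 against 7, 1 for day 14 against 3, 10 for the mean and 9 in the F test. In that block fit 24 of 42 named results passed. The labels give no shared animal or batch for a replicate number, and 7 of 18 same-number pairs deviated together at a correlation above 0.1 (-0.105 to 0.793), so the block was not taken as the design. The 3 pairs of sham and day 7 did deviate together (0.459, 0.534 and 0.793), and 8 of 12 libraries correlated best with their own number. Fits of only the 2 groups gave 2, 1, 5, 0, 0 and 155 in the order above, and 1, 1 and 1 shared. Array weights gave 699, 131, 479, 243, 318 and 147, 393 for the mean, 781 in the F test, and 103, 288 and 98 shared. An unadjusted p with a log2 of at least 1 gave 37, 34, 30, 27, 21 and 20, 48 in the F test, and 9, 12 and 13 shared. Without the 2 libraries that stood apart there were 1101, 173, 733, 317, 418 and 309, 687 for the mean, 1066 in the F test, and 139, 474 and 117 shared; all 42 named results passed. A preparation term gave 540, 176, 208, 184, 217 and 41, 382 for the mean, 553 in the F test, and 110, 144 and 64 shared. Averaging near-identical libraries gave 1, 0, 0, 1, 0 and 0, 0 for the mean, 0 in the F test and 0, 0 and 0 shared. Averaging with the term gave 0, 1, 0, 0, 0 and 0, 1 for the mean, 0 in the F test and 0, 0 and 0 shared. Leaving out each library in turn gave ranges of 3 to 40 on day 3, 4 to 26 on day 7, 5 to 21 on day 14, 0 to 8 for day 7 against 3, 0 to 15 for day 14 against 7, 0 to 4 for day 14 against 3, 5 to 38 for the mean and 5 to 33 in the F test; shared calls ran from 2 to 18, 2 to 14 and 4 to 16. The highest values came without sham library 3, except 40, which came without day 7 library 3. Camera with an estimated correlation called 14 of 99 list tests against 48. Of those 48, 36 passed without the 2 libraries and 1 reversed, the mitochondrially encoded genes on day 7 (adjusted p = 0.0028; adjusted p = 0.28 with an estimated correlation). The stricter list held 22097, 20957 and 21959 peaks on days 3, 7 and 14, against 40195, 34136 and 38655. Within it 10182 were gained and 9888 lost on day 3, 7508 and 8349 on day 7, and 9851 and 9692 on day 14. Counting 1 shared base gave 14639 and 4465, 8951 and 6191, and 13383 and 4674. RNA medians of genes with gained peaks were 0.0156, -0.00459 and 0.0225 and of genes with lost peaks -0.00839, -0.00202 and 0.00478. Without the 2 libraries gained genes were at 0.0108 on day 3 and 0.0188 on day 14, and lost genes at 0.00603, which reversed, -0.000233 and 0.0198. Genes with a peak in 1 list and none in the other were at 0.1, 0.000405, which reversed, and 0.0796 when gained, and at 0.0461 and 0.0231, which reversed, and 0.00114 when lost. The same without the 2 libraries gave 0.0301, -0.00567 and 0.0187 when gained and 0.0596 and 0.0269, which reversed, and 0.0337 when lost. A pseudocount of 1, median-of-ratios scaling, robust eBayes, merged peaks, 80% overlap, equal peak numbers and exonic overlap moved no count by more than 1.5 times.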

Other observations

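Receptor and pain-signalling transcripts carried m6A in every group: all 16 tested transmitter receptor genes and all 16 pain-related signalling genes had a peak in sham and on days 3, 7 and 14. Immediate early genes did too, at 10 of 10. Of all tested genes, 74.4, 85.5, 76.6 and 85.1% had a peak in these lists, and no test of the groups against that share was made. Cytosolic ribosomal protein genes had a peak for 3 of 19 in sham, 14 on day 3, 5 on day 7 and 12 on day 14. Of those peaks few were strict, with 2, 3, 2 and 3 genes holding 1. Among the m6A enzymes, Virma, a scaffold of the writer complex, had 6, 7, 4 and 6 peaks in sham and on days 3, 7 and 14, and Mettl5, which methylates ribosomal RNA, had 0, 2, 0 and 2.

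Among 4 clock genes looked at, Dbp alone passed. Nr1d1, a clock repressor, was at 13.3 FPKM in sham and 19.5, 13.9 and 21.4 on days 3, 7 and 14, and Ciart at 2.85, 4.6, 3.35 and 5.12. Arntl, the opposing activator, was at 2.53, 1.78, 2.27 and 1.83. The other 3 were picked after Dbp was seen to rise, and no test was made of them as a group. Hour of sampling was not part of the comparison, so injury and time of day were not told apart for Dbp or these genes.

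Lung and liver transcripts marked single libraries of day 3. Scgb1a1, a lung secretory protein, was at 118 FPKM in day 3 library 1 and 0 in every other library, and Sftpc, a surfactant protein, at 23.2 there and at most 0.32 elsewhere. All 10 lung genes were highest in day 3 library 1 and all 10 liver genes in day 3 library 2. Alb, serum albumin, was at 85.4 FPKM in day 3 library 2, 29.5 in sham library 1 and 4.99 in sham library 2. Near-identical libraries differed more than 2-fold for 0.874 to 1.43% of genes at 2 FPKM or more.

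Peaks in the liver genes Mup3 (fold enrichment 84.5 on day 7), Mup7 (153 on day 14) and Fabp1 (114 on day 14) had no base in the sham list. Mup3 was at 0 FPKM in all day 7 input libraries. Among genes with a mean FPKM of at least 1, the strict day 14 peak of highest fold enrichment with no base in sham lay in the 3′ UTR of Gapdh (221), a glycolytic enzyme.

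Inhibitory-neuron genes had a median of 0.17 on day 14 (adjusted p = 0.0067; adjusted p = 0.24 with an estimated correlation; median 0.10 and 0.024 without both libraries that stood apart), and excitatory dorsal horn genes 0.24 on day 3 (adjusted p = 0.048; adjusted p = 0.43 with an estimated correlation) and 0.26 on day 14 (adjusted p = 0.045; adjusted p = 0.43 with an estimated correlation); without both libraries that stood apart neither excitatory call held (medians 0.06 and 0.07; adjusted p = 0.097 and 0.051). Cell cycle genes had a median of 0.32 on day 3 (adjusted p = 0.0072; adjusted p = 0.37 with an estimated correlation; median 0.21, adjusted p = 0.17 without both libraries that stood apart). Oxidative phosphorylation genes had a median of 0.26 on day 3 (adjusted p = 0.0017; adjusted p = 0.48 with an estimated correlation; median 0.07 and 0.016 without both libraries that stood apart) and 0.19 on day 14 (adjusted p = 0.019; adjusted p = 0.56 with an estimated correlation; median 0.02, adjusted p = 0.24 without both libraries that stood apart). Antigen presentation genes had a median of 0.26 on day 14 (adjusted p = 0.0072; adjusted p = 0.29 with an estimated correlation; median 0.14, adjusted p = 0.097 without both libraries that stood apart), and reactive astrocyte genes 0.22 on day 3 (adjusted p = 0.0024; adjusted p = 0.19 with an estimated correlation; median 0.09, adjusted p = 0.051 without both libraries that stood apart) and 0.10 on day 7 (adjusted p = 0.0045; adjusted p = 0.21 with an estimated correlation). In limma 0 genes of these lists passed. In the inhibitory-neuron list on day 14, Npy (0.98) and Gal (1.82), named above as induced by injury, had the smallest p. Of its 12 genes, 10 were positive and 3 are also in other lists. Irf7, an interferon regulator, was at 3 and 2.58 FPKM in sham libraries 1 and 2 and 0.731 in sham library 3, and Isg15 at 6.28, 5.94 and 0.653.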
